A study of Homo sapiens with 9 samples.

How the data were processed

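RNA was measured in 9 cultures of A549, an established human lung adenocarcinoma cell line. The labels place 3 libraries in each of 3 groups: cells with a scrambled control short hairpin RNA (shRNA, a small hairpin that directs the degradation of a matching transcript), cells with an shRNA against AKR1B1, and cells with an shRNA against SORD. The control libraries are named plko in their titles and scrambled controls in their treatment label, and both names were taken to mean the same group. These names do not settle whether the control cells carried a scrambled hairpin or a vector without one. The series describes the 3 libraries of a group as biological replicates. The sources used here do not say whether they were separate transductions or separate dishes of 1 transduced population, so p-values measure the spread between these libraries, which may be narrower than that between independent knockdowns. Each target was lowered by 1 shRNA label and compared with 1 control label, so effects of a single hairpin sequence or of a single control population cannot be separated from the group.

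Per the labels' protocols, cells were grown in medium with 5% serum, RNA was taken with Qiazol and the miRNeasy Mini Kit, and libraries were made with a poly(A)-selecting, strand-marking kit (TruSeq stranded mRNA). Per the submitters' processing notes, the tools named are cutadapt 1.9.1, STAR 2.5.2b, featureCounts 1.5.1 of Subread and DESeq2 1.12.3, and the genome build is GRCh37. Their usual roles are adapter trimming, alignment, counting of reads per gene and testing. The deposited table holds the authors' counts of reads per Ensembl gene, as whole numbers without normalization, for 57905 gene IDs and the 9 libraries. The gene annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap an antisense partner, and genes with near-identical copies, are therefore uncertain: reads can be lost or shared between AKR1B1 and its processed pseudogenes, between AKR1B10 and AKR1B15, between SORD and the pseudogene SORD2P, and within the CEACAM, AKR1C and MUC5 families.

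Total counts per library ranged from 32436524 to 43044456. Values per gene are given as CPM, the deposited counts divided by the TMM-scaled library size in units of 1e6 counts. Gene names came from a table of gene IDs and symbols, which matched 51996 of the 57905 IDs. Gene types, transcript lengths and GC content came from GENCODE 29, which gave a type for 52338 IDs. That annotation is on another genome build than the counts, so no coordinates are given. In the 30 gene lists, 7 entries matched no single gene ID and were left out: ACACA, UHRF1, CD24, PECAM1, HIST1H2AE, HIST1H3B and HIST1H4B.

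The main test was edgeR 4.0.16 in R 4.3.3: TMM scaling, the default expression filter by group, a quasi-likelihood negative binomial model with 1 mean per group over all 9 libraries, and Benjamini-Hochberg adjustment within each of 3 comparisons (shAKR1B1 against control, shSORD against control, shAKR1B1 against shSORD). The filter kept 16916 genes. A gene was called where its adjusted p was under 0.05, and "rose", "fell", "higher" and "lower" refer to such calls. The common biological coefficient of variation was 6.59%. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the test's F statistic. Fitted log2 fold changes used a prior count of 0.125. All adjusted p-values of single genes below come from this edgeR test unless another tool is named, and each comparison has n = 3 libraries per group.

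Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) where at least 5 members passed the filter, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera asks whether the test statistics of a list's members are on average higher or lower than those of the other genes. As alternatives the correlation was estimated from the data, and fry, a test of the list alone, was run. Across genes, fold changes correlated with expression level (Spearman -0.183 with shAKR1B1 and -0.23 with shSORD against control, 0.0371 between the knockdowns). The list tests did not match genes on level, so part of the fall of lists of abundant genes may follow this trend. The test, the lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The rule named AKR1B1 and SORD, then, for each knockdown against control, the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean of at least 50 counts per library and all knockdown libraries beyond all control libraries. "Largest" refers to the genes that meet these conditions. It further named the 10 genes with the largest change in whichever knockdown changed them less, among those meeting these conditions in the same direction in both knockdowns, the 5 largest differences each way between the knockdowns, up to 4 list members with the lowest adjusted p, and 16 genes of epithelial and mesenchymal state, TGF-beta signalling and proliferation, of which 1 is not reported here. Genes named outside this rule were chosen after their values were seen, and 3 further lists (liver-type, intestinal and their transcription factors) were written after the largest rises were seen, without the genes that prompted them.

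The comparisons with control share the same 3 control libraries. The overlap expected from noise in those libraries alone was simulated with 100 sets of unchanged libraries drawn from the real means, dispersions and library sizes. The alternatives were edgeR's RLE scaling in place of TMM, no expression filter, a stricter filter (mean CPM of at least 1) and a fit of only the groups compared. Further alternatives were the replicate number as a block, each library left out in turn, DESeq2 1.42.0 and the list tests above. An offset for GC content was chosen after the data were seen. The pipeline was tested on simulated counts for 16916 genes, with 200 changed in each knockdown, 50 at each size. For shAKR1B1 against control, edgeR recovered 4% of the 1.2-fold changes, 66% of the 1.5-fold changes, 80% of the 2-fold changes and 100% of the 4-fold changes, with 6.02% false calls. For shSORD against control the shares were 16%, 80%, 84% and 100%, with 4.76% false calls. With so few changed genes, DESeq2 gave 11.9% and 9.03% false calls. The data gave 9716 and 9565 calls, so the adjusted threshold was less strict than in the simulation. These shares therefore do not measure the recovery reached in the data, and scaling with most genes changed was not tested. Replicates were compared by a chi-square of their counts per degree of freedom, which ranged from 2.39 (control replicates 2 and 3) to 27.0 (shSORD replicates 2 and 3). It was at least 12.9 within shSORD, against at most 5.83 within control and 6.37 within shAKR1B1. The main fit pooled the spread over these groups, so its p-values for shSORD comparisons may be too small. No pair agreed within sampling noise, so all 9 libraries were counted.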

Results

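The series asks how the polyol pathway, which turns glucose into fructose by way of sorbitol, relates to the aggressiveness of cancer cells. Aldose reductase (AKR1B1) reduces glucose to sorbitol, and sorbitol dehydrogenase (SORD) oxidises sorbitol to fructose. Transcriptomes of A549 lung adenocarcinoma cells were compared between 3 control libraries, 3 libraries with AKR1B1 knockdown (shAKR1B1) and 3 with SORD knockdown (shSORD). Total counts were 37073786, 38843912 and 40248882 in the control libraries, 32436524, 40297506 and 43044456 with shAKR1B1 and 37655976, 40099716 and 39444992 with shSORD. On the first principal component, with 59.2% of the variance, the control libraries (-57.0 to -55.6) stood apart from shAKR1B1 (31.96 to 39.77) and shSORD (15.5 to 26.6). The second component, with 22.1%, separated shAKR1B1 (24.4 to 28.7) from shSORD (-38.2 to -29.9).

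Both knockdowns lowered their target strongly, and each also lowered the other enzyme to a smaller degree. AKR1B1 (ENSG00000085662) was at 1416 ± 34.7 CPM in control cells (SD, n = 3) and at 153.8 ± 11.7 CPM in shAKR1B1 cells, 10.9% of control (log2 fold change -3.20, SE 0.0754, adjusted p = 5.4e-13). In shSORD cells AKR1B1 was at 1063 ± 103 CPM, 75.1% of control (log2 fold change -0.41, adjusted p = 0.000131). SORD (ENSG00000140263) was at 42.9 ± 1.19 CPM in control cells and at 8.62 ± 0.414 CPM in shSORD cells, 20.1% of control (log2 fold change -2.32, SE 0.0666, adjusted p = 3.65e-12). In shAKR1B1 cells it was at 30.6 ± 0.411 CPM, 71.1% of control (log2 fold change -0.49, adjusted p = 6.43e-06). The pseudogene SORD2P, close in sequence to SORD, had 32 to 38 counts per control library, 30 to 41 with shAKR1B1 and 8 to 11 with shSORD. AKR1B10, the paralog of AKR1B1 that reduces retinal and other aldehydes, was the far more abundant transcript at 4947 ± 37.0 CPM in control cells. It rose with shAKR1B1 (6762 ± 154 CPM, log2 fold change 0.45, adjusted p = 4.57e-07) and fell with shSORD (4355 ± 107 CPM, -0.18, adjusted p = 0.00197).

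**Figure D1:**
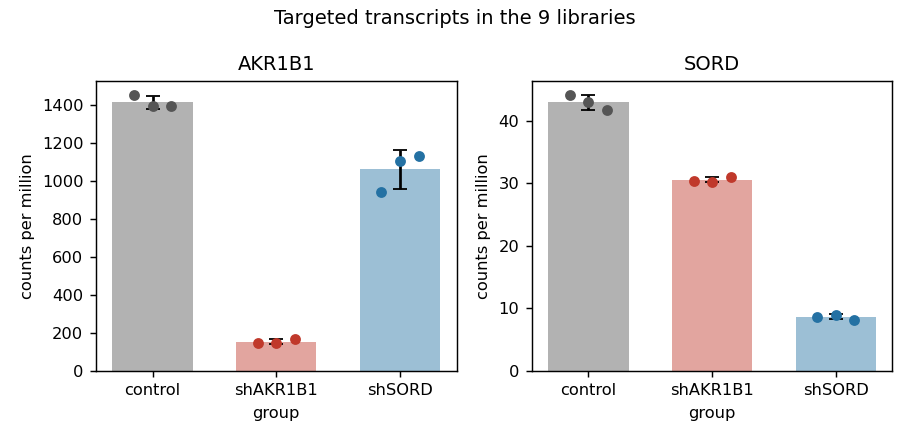
CPM of AKR1B1 (left) and SORD (right) in the 3 groups. Bars are group means with SD, and points are the 3 libraries of each group. AKR1B1 fell from 1416 to 153.8 CPM with shAKR1B1, and SORD from 42.9 to 8.62 CPM with shSORD.

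With AKR1B1 knockdown the epithelial list was higher, and the mesenchymal, matrix and TGF-beta target lists were lower. None of these calls held with an estimated correlation (adjusted p = 0.0973, 0.295, 0.0973 and 0.116). In all, 4705 genes rose and 5011 fell of 16916 tested, and among the 2093 that changed at least 2-fold, 1429 rose and 664 fell. Among the largest rises, BPIFB1, a secreted protein of airway epithelium, went from 0.114 ± 0.056 to 5.26 ± 0.329 CPM (44.5-fold), and PKHD1, the ciliary protein fibrocystin of renal and bile duct epithelium, from 0.175 ± 0.0476 to 7.87 ± 0.329 CPM (43.8-fold). The olfactory receptor OR51E1 rose 31.7-fold, the histamine-degrading enzyme HNMT 20.9-fold, the alcohol dehydrogenase ADH6 19.9-fold and the choline transporter-like SLC44A4 19.7-fold. TM4SF20, a membrane protein of the tetraspan superfamily, rose 17.6-fold from 12.1 ± 0.341 to 212.7 ± 22.8 CPM, the actin-severing SCIN 17.5-fold, the sugar transporter SLC5A9 17.0-fold and CXXC4, an inhibitor of Wnt signalling, 16.2-fold (all adjusted p at or below 2.38e-08). Each control library held only 3 to 7 counts of BPIFB1, 5 to 9 of PKHD1, 3 to 8 of HNMT and 3 to 9 of SLC44A4. SCIN had 10 to 12 and CXXC4 9 to 12, so the sizes of these folds are uncertain.

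The largest fall with shAKR1B1 was in DLC1, which fell from 7.55 ± 0.763 to 0.166 ± 0.12 CPM (43.2-fold), resting on 2 to 12 counts per knockdown library, and without shAKR1B1 replicate 2 its log2 fold change was -6.10 in place of -5.43. The matricellular protein SPARC fell 31.4-fold from 10.4 ± 0.229 CPM, the proteoglycan SPOCK1 27.0-fold from 16.4 ± 0.555 CPM and the adhesion receptor TENM2 19.1-fold from 12.9 ± 0.75 CPM. The calcium-activated potassium channel KCNMA1 fell 17.0-fold, the gelatinase MMP2 17.0-fold, DPYSL3, a cytoskeletal regulator of growing neurites, 13.6-fold, SHISAL1 12.1-fold, the BMP-binding BMPER 11.5-fold and the homeobox gene ALX4 10.7-fold (all adjusted p at or below 4.58e-09).

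Gene lists fixed in advance were compared with the 27.8% of all tested genes that rose and the 29.6% that fell in this comparison. Unless a second pair of numbers is given, counts adjusted over the list alone were the same. Of 35 epithelial markers, 28 rose and 3 fell with shAKR1B1 (median log2 fold change 0.87, camera adjusted p = 4.31e-09, but adjusted p = 0.0973 with an estimated correlation). E-cadherin (CDH1) rose 2.13-fold from 141.2 ± 4.06 to 300.6 ± 15.2 CPM (log2 fold change 1.09, SE 0.0615, adjusted p = 1.78e-09), and EPCAM, an epithelial adhesion molecule, rose 3.43-fold. The tight junction protein cingulin (CGN) rose 4.95-fold and the desmosomal plakoglobin JUP 2.55-fold. Among 39 mesenchymal markers 24 fell and 5 rose (median -0.67, adjusted p = 1.4e-06, with an estimated correlation adjusted p = 0.295). COL5A1, a fibrillar collagen chain, fell 10.2-fold from 100.5 ± 5.92 CPM and the collagen cross-linking enzyme LOXL2 by 1.63 on the log2 scale, beside SPARC and MMP2. N-cadherin (CDH2) fell 2.15-fold (log2 fold change -1.10, adjusted p = 1.33e-08) and vimentin (VIM) 1.17-fold (-0.23, adjusted p = 0.000392), while fibronectin (FN1) rose 1.38-fold (adjusted p = 0.000275). The transcription factors of epithelial-mesenchymal transition did not move together: TWIST1 fell 1.63-fold and ZEB2 rose 2.63-fold from 0.788 ± 0.0865 CPM. ZEB1 (25.8 ± 0.958 against 25.8 ± 1.35 CPM, adjusted p = 0.99), SNAI1 (log2 fold change 0.21, adjusted p = 0.187) and SNAI2 (-0.46, adjusted p = 0.452) did not pass the test.

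TGF-beta target genes were lower with shAKR1B1. Of 29 measured, 16 fell and 4 rose (17 and 5 adjusted over the list alone; median -0.25, adjusted p = 4.31e-09, with an estimated correlation adjusted p = 0.116). The cytokine IL11 fell 9.41-fold, from 38.7 ± 1.07 to 4.11 ± 0.0802 CPM, and PMEPA1, a feedback inhibitor of the pathway, 7.96-fold, from 308.7 ± 0.916 to 38.7 ± 3.56 CPM. The basement membrane collagen COL4A1 fell by 1.86 on the log2 scale, and the secreted TGFBI fell 2.48-fold from 1431 ± 8.87 CPM. The ligand TGFB1 fell 2.45-fold, from 114.7 ± 3.94 to 46.7 ± 2.37 CPM (log2 fold change -1.29, SE 0.0815, adjusted p = 5.71e-09), and TGFB2 1.69-fold (adjusted p = 7.55e-05). The list of ligands, receptors and SMADs as a whole did not pass (4 rose and 8 fell of 19, adjusted p = 0.515, with a median of 0.05, a mean of -0.10 and a test direction of down). Matrix remodelling genes and integrins fell as a list, with 18 of 37 lower and 11 higher (19 and 11 adjusted over the list alone; median -0.22, adjusted p = 0.00447, with an estimated correlation adjusted p = 0.0973). The laminin chain LAMA3 fell by 2.04 and the metalloprotease ADAM12 by 2.26 on the log2 scale, whereas the laminin chain LAMB3 rose (log2 fold change 1.49). Fibroblast markers, 7 of whose 9 measured members are also mesenchymal markers, stood at 4 lower and 1 higher (median -1.21, adjusted p = 0.0632). That list passed without control replicate 2, control replicate 3 or shAKR1B1 replicate 2 (adjusted p = 0.0441, 0.0407 and 0.0424).

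Lists of replication, glycolysis, fatty acid synthesis and ATF4-related genes were also lower with shAKR1B1, each with the preset correlation only. Of 26 genes of the G1/S transition, 25 fell and 0 rose (median -0.59, adjusted p = 2.97e-09, with an estimated correlation adjusted p = 0.295). The flap endonuclease FEN1 fell by 0.97, the replicative helicase subunits MCM5 by 0.90 and MCM2 by 0.70 on the log2 scale. G2/M genes did not pass as a list (13 fell and 1 rose of 32, adjusted p = 0.121, and 0.00575 with no expression filter), with CDC20 and PLK1, which drive mitosis, at -0.77 and -0.71, and the proliferation marker MKI67 at -0.06 (adjusted p = 0.411). Of 23 glycolysis genes 18 fell and 1 rose (median -0.38, adjusted p = 0.000227, with an estimated correlation adjusted p = 0.309). PFKFB3, which makes the activator of phosphofructokinase, fell 1.76-fold from 588.7 ± 1.85 CPM, phosphoglycerate kinase (PGK1) 1.69-fold and the glucose transporter SLC2A1 by 0.69 on the log2 scale. Fatty acid synthesis fell with 14 of 21 lower and 3 higher (median -0.29, adjusted p = 0.0032, with an estimated correlation adjusted p = 0.0973). Fatty acid synthase (FASN) fell 2.06-fold from 479.6 ± 16.0 CPM, and the desaturases FADS2 and SCD fell by 0.98 and 0.62 on the log2 scale. ATF4 and unfolded protein response genes fell, 16 of 30 against 6 higher (16 and 7 adjusted over the list alone; adjusted p = 0.0182, with an estimated correlation adjusted p = 0.295, and 0.0548 with the stricter filter). ATF4 itself fell by 0.63, the amino acid transporter SLC7A5 by 1.04 and TRIB3, a pseudokinase induced by ATF4, by 0.79 on the log2 scale.

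Alveolar and airway markers rose, 7 of 14 with 2 lower (median 0.45, adjusted p = 0.00291, with an estimated correlation adjusted p = 0.295, and 0.073 with no expression filter). The mucin MUC5AC (log2 fold change 2.99), the pioneer factor FOXA1 (1.95) and CEACAM6 (1.66) led the list. Of its 26 genes 12 were below the filter, among them the surfactant genes SFTPA1, SFTPA2 and SFTPB and the lung transcription factor NKX2-1, with at most 4 counts in any library. The other lists did not pass with shAKR1B1. Among p53 targets 12 of 25 fell and 4 rose (13 and 4 adjusted over the list alone; adjusted p = 0.0754, 0.0441 without control replicate 2 and 0.00878 with no expression filter). The cell cycle inhibitor CDKN1A fell 1.75-fold, the nuclease AEN by 0.90 and the stress cytokine GDF15 by 1.17 on the log2 scale. The polyol and fructose list had 3 higher and 4 lower of 9 (adjusted p = 0.282, median 0.03, mean -0.25), with the glycerate kinase GLYCTK up by 1.28. Counts higher and lower were 9 and 11 of 24 YAP/TAZ targets (9 and 12 adjusted over the list alone; adjusted p = 0.324), 2 and 4 of 13 pentose phosphate genes (0.783) and 3 and 1 of 11 hexosamine genes (0.85). They were 9 and 25 of 73 oxidative phosphorylation genes (9 and 24 adjusted over the list alone; 0.384), 3 and 13 of 27 TCA cycle genes (0.355) and 6 and 16 of 25 cholesterol synthesis genes (0.355). With no expression filter the last 3 lists passed, lower (adjusted p = 0.0475, 0.0368 and 0.0368). For NRF2 targets they were 13 and 8 of 30 (0.392), for the hypoxia response 7 and 9 of 25 (0.865), for interferon-stimulated genes 6 and 13 of 33 (0.865), for NF-kappaB and cytokine genes 4 and 9 of 25 (0.515) and for stem cell markers 8 and 6 of 17 (0.691).

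With SORD knockdown the epithelial list was higher and the G1/S and glycolysis lists lower, without a fall of the mesenchymal or TGF-beta target lists. None of these calls held with an estimated correlation (adjusted p = 0.159, 0.523 and 0.523). In all, 4655 genes rose and 4910 fell, and among the 1881 that changed at least 2-fold, 1357 rose and 524 fell. The largest rise was in CRYAB, the small heat shock protein alpha-B crystallin, from 0.535 ± 0.139 to 10.8 ± 1.2 CPM (19.99-fold, log2 fold change 4.32, SE 0.167, adjusted p = 5.74e-11). The coagulation factor genes F10 and F7 rose 17.7-fold and 10.4-fold to 2.24 ± 0.623 and 3.6 ± 0.877 CPM, and PKHD1 rose 15.2-fold. These folds rest on 3 to 6, 10 to 15 and 5 to 9 counts per control library for F10, F7 and PKHD1. The sphingolipid desaturase DEGS2 rose 11.7-fold, TM4SF20 11.02-fold, the adhesion molecules CEACAM5 and CEACAM7 10.8-fold and 9.88-fold, and the membrane skeleton protein ankyrin-G (ANK3) 9.37-fold. DIP2C-AS1, an antisense gene listed as protein-coding in GENCODE 29, rose 10.9-fold from 4 to 13 counts per control library, with reads that cannot be assigned to a strand here.

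The largest fall with shSORD was in HHIP, an inhibitor of hedgehog signalling, from 2.62 ± 0.158 to 0.0835 ± 0.0122 CPM (30.2-fold, 3 to 4 counts per knockdown library, adjusted p = 7.68e-10). TENM2 fell 18.6-fold, the netrin receptor UNC5D from 8.09 ± 0.338 to 0.617 ± 0.1 CPM, the synaptic factor INSYN2A 11.8-fold and the collagen COL21A1 11.3-fold. The dopamine receptor DRD1 fell 10.7-fold, DLC1 10.7-fold, the potassium channel subunit KCNV1 8.62-fold, the monocarboxylate transporter family member SLC16A6 8.49-fold and the GDNF receptor GFRA1 8.27-fold (all adjusted p at or below 2.49e-08).

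Against control, 27.5% of all tested genes rose and 29% fell with shSORD. Of 35 epithelial markers, 30 rose and 1 fell, and 31 and 1 adjusted over the list alone (median 0.61, adjusted p = 1.19e-10, with an estimated correlation adjusted p = 0.159). CDH1 rose 2.21-fold to 311.8 ± 23.8 CPM (adjusted p = 1.6e-09), EPCAM 5.11-fold, CGN 4.04-fold and the keratin KRT19 by 1.43 on the log2 scale. Mesenchymal markers went both ways, with 16 of 39 higher and 13 lower (16 and 15 adjusted over the list alone; median 0.07, mean 0.20, test direction down, adjusted p = 0.85). SPARC fell 6.11-fold, the Wnt ligand WNT5A by 2.68 on the log2 scale, FN1 2.27-fold to 539.6 ± 89.2 CPM, TWIST1 2.59-fold and the hyaluronan receptor CD44 by 0.92. CDH2 rose 1.47-fold (adjusted p = 7.99e-06), SNAI1 1.38-fold (adjusted p = 0.0076) and the actin-binding TAGLN 3.74-fold. VIM was at 0.07 (adjusted p = 0.16, 0.0425 without shSORD replicate 3 and 0.0229 with the stricter filter), ZEB1 at 0.02 (adjusted p = 0.821) and ZEB2 at 0.22 (adjusted p = 0.511). SNAI2, with 0 to 12 counts per shSORD library, fell by 1.57 (adjusted p = 0.0345). That call ended without control replicate 1, control replicate 3, shSORD replicate 1 or shSORD replicate 2 (adjusted p = 0.0729, 0.105, 0.107 and 0.0865) and with DESeq2 (0.054), and the value was -3.21 without shSORD replicate 3. Fibrillar collagens rose unevenly: COL1A2 was at 1.11, 5.29 and 1.76 CPM in shSORD replicates 1, 2 and 3 and at 0.106 to 0.304 CPM in control libraries (log2 fold change 3.79, and 2.87 without shSORD replicate 2). COL3A1 was at 0.647, 2.71 and 1.4 CPM (log2 fold change 3.66, and 3.02 without shSORD replicate 2), and COL1A1 rose by 1.28. Of 9 fibroblast markers 6 rose and 1 fell (6 and 3 adjusted over the list alone; median 1.98, adjusted p = 0.395).

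TGF-beta target genes split with shSORD, 11 of 29 higher and 8 lower (11 and 9 adjusted over the list alone; median -0.00, adjusted p = 0.911). TGFB1 fell 2.37-fold to 48.3 ± 6.56 CPM (adjusted p = 1.23e-08), while TGFB2 was at 0.03 (adjusted p = 0.866). IL11 fell 2.34-fold and PMEPA1 1.58-fold. TAGLN rose as above, heme oxygenase HMOX1 rose 1.63-fold and the integrin ITGB6 by 1.24 on the log2 scale, and TGFBI was at -0.06 (adjusted p = 0.391). The ligand, receptor and SMAD list had 11 of 19 higher and 3 lower (12 and 3 adjusted over the list alone; adjusted p = 0.27), with the latent TGF-beta binding protein LTBP1 up by 1.80. Matrix remodelling genes and integrins had 16 of 37 higher and 11 lower (18 and 12 adjusted over the list alone; adjusted p = 0.598), with LAMB3 up 3.73-fold, the integrin ITGA1 up by 2.17 and ADAM12 lower by 1.65 (log2 fold change -1.65).

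Of 26 G1/S genes, 25 fell and 0 rose with shSORD (median -0.55, adjusted p = 1.57e-10, with an estimated correlation adjusted p = 0.523), led by MCM6 (log2 fold change -0.98) and the replication factor GINS1 (-0.87). G2/M genes fell, 23 of 32 with 1 higher (median -0.27, adjusted p = 0.000227, with an estimated correlation adjusted p = 0.6), led by the ubiquitin-conjugating UBE2C (-1.19), CDC20 (-0.82) and the survivin gene BIRC5 (-0.67), and MKI67 fell 1.21-fold (adjusted p = 0.00104). Of 23 glycolysis genes 19 fell and 1 rose (20 and 1 adjusted over the list alone; median -0.39, adjusted p = 0.00163, with an estimated correlation adjusted p = 0.523). Aldolase A (ALDOA) and pyruvate kinase (PKM) fell by 0.58 and 0.53, whereas the glucose transporter SLC2A3 rose 2.17-fold (adjusted p = 9.02e-10). Nuclear-encoded oxidative phosphorylation genes fell, 39 of 73 with 2 higher (median -0.17, adjusted p = 0.00187, with an estimated correlation adjusted p = 0.541), with the ATP synthase subunit ATP5MC1 at -0.81, cytochrome c (CYCS) at -0.85 and CYC1 at -0.57. Fold changes with shSORD correlated at -0.23 with expression level (Spearman), and these list tests did not match genes on level. NF-kappaB and cytokine genes were lower for 12 of 25 and higher for 4 (adjusted p = 0.0356, with an estimated correlation adjusted p = 0.523), a call that ended without shSORD replicate 3 (adjusted p = 0.145) and with the GC offset (0.11). The chemokine CXCL1 fell by 1.88 and the cyclooxygenase PTGS2 by 1.27 on the log2 scale. The polyol and fructose list was lower for 6 of 9 and higher for 1 (adjusted p = 0.0328, with an estimated correlation adjusted p = 0.523), including L-xylulose reductase DCXR (-0.48). Without shSORD replicate 3 its adjusted p was 0.145, and without AKR1B1 and SORD in the list it was 0.822.

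The other lists did not pass with shSORD. FASN fell by 0.92 and SREBF1, the transcription factor of lipid synthesis, by 0.57 on the log2 scale, but of 21 fatty acid synthesis genes 10 fell and 4 rose (adjusted p = 0.112, and 0.0108 with no expression filter). TCA cycle genes had 16 of 27 lower and 3 higher (16 and 4 adjusted over the list alone; adjusted p = 0.064, 0.0483 without shSORD replicate 2 and 0.000771 with no expression filter). Of 25 p53 targets 13 rose and 7 fell (adjusted p = 0.395), with CDKN1A up 1.33-fold, the mitochondrial quality gene SPATA18 up by 1.34 and the death receptor TNFRSF10B up by 0.41. Counts higher and lower were 8 and 3 of 14 alveolar and airway markers (adjusted p = 0.339), with the mucin MUC5B at -1.78, 7 and 15 of 30 ATF4 and unfolded protein response genes (0.339), 14 and 5 of 33 interferon-stimulated genes (0.312) and 5 and 12 of 30 NRF2 targets (0.85). They were 10 and 8 of 24 YAP/TAZ targets (10 and 9 adjusted over the list alone; 0.853), 1 and 6 of 13 pentose phosphate genes (0.395), 2 and 3 of 11 hexosamine genes (0.85) and 5 and 13 of 25 cholesterol synthesis genes (0.339, and 0.0371 with no expression filter). For the hypoxia response they were 8 and 11 of 25 (0.874), and for stem cell markers 7 and 7 of 17 (8 and 7 adjusted over the list alone; 0.711).

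**Figure D2:**
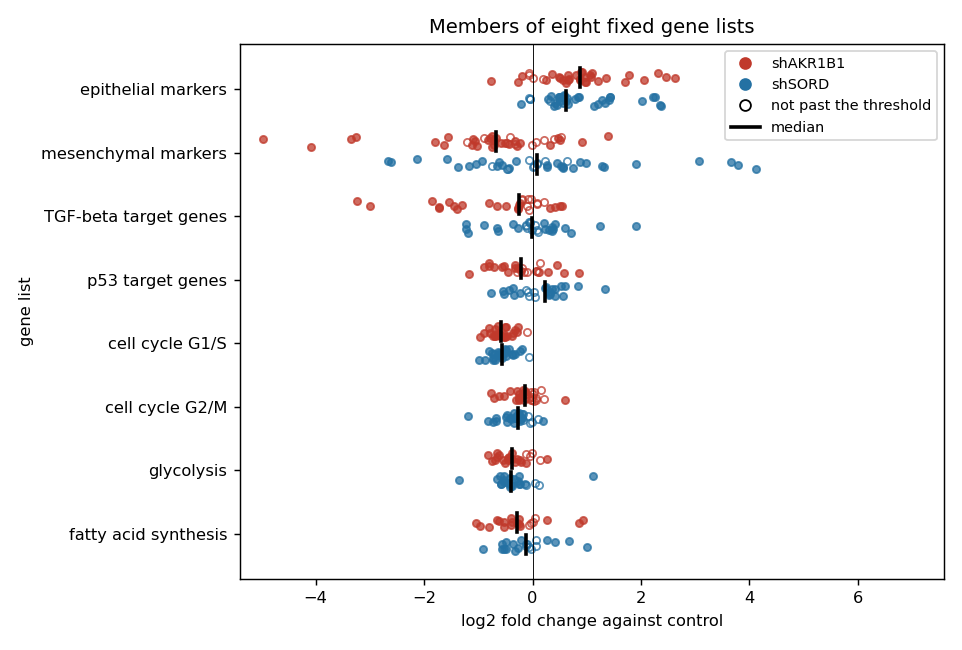
Log2 fold changes against control (horizontal axis) of the measured members of 8 gene lists (vertical axis). Each point is a gene, red for shAKR1B1 and blue for shSORD, filled where its adjusted p is under 0.05, and black bars are medians. Epithelial markers lie to the right in both knockdowns (medians 0.87 and 0.61) and G1/S genes to the left (-0.59 and -0.55), while mesenchymal markers have medians of -0.67 and 0.07.

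Genes called in both knockdowns mostly went the same way. Of 7241 called in both, 6931 (95.7%) shared their direction, 3320 higher and 3611 lower, and 310 went in opposite directions. Independent lists of these sizes would share 1295 higher and 1454 lower genes, and unchanged groups simulated against the same controls shared at most 2 genes per set. Such groups yield almost no calls, so this count does not show how many of the shared calls come from the shared controls. The genes with the largest changes common to both were TENM2, PKHD1, CRYAB, F10, TM4SF20, DIP2C-AS1, DLC1, F7, INSYN2A and CEACAM7. TENM2 was at 0.669 ± 0.0992 CPM with shAKR1B1 and 0.688 ± 0.123 CPM with shSORD, against 12.9 CPM in control cells, and did not differ measurably between the knockdowns (log2 difference -0.03, SE 0.208, adjusted p = 0.928). PKHD1 differed in size, 2.89-fold higher with shAKR1B1 than with shSORD (adjusted p = 3.93e-07). Across all 16916 genes, which are not independent replicates, the fold changes of the knockdowns had a correlation of 0.771, against a mean of 0.505 in the simulated unchanged groups, and 80.7% had the same sign, against 66.8%. The covariance was 0.434 against a simulated mean of 0.0243, a difference of 0.41. The 3 control libraries cannot be split into 2 parts of at least 2 libraries, so part of the excess may come from the shared controls.

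**Figure D3:**
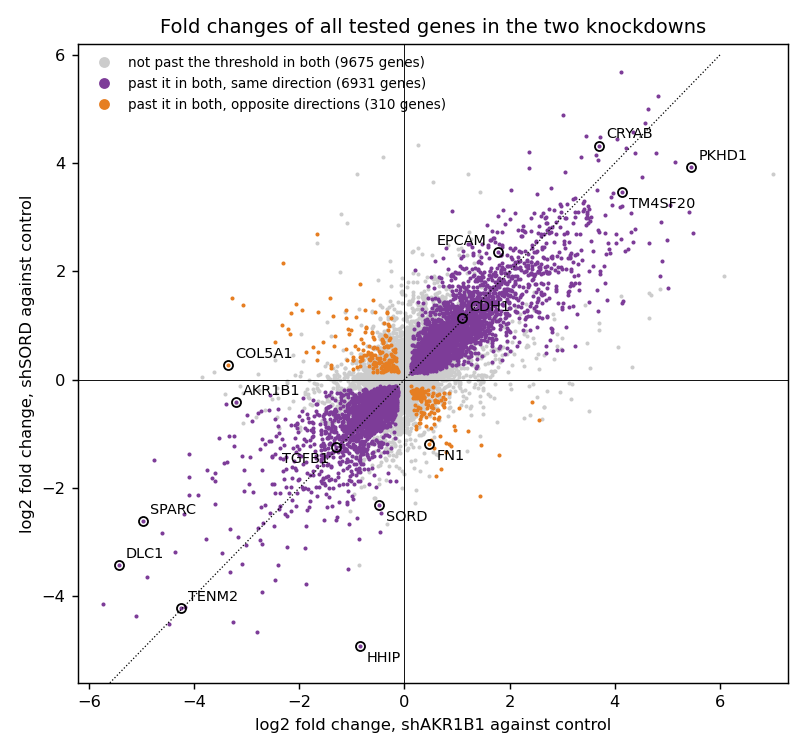
Log2 fold change of each of 16916 tested genes with shAKR1B1 (horizontal axis) and with shSORD (vertical axis) against the same control libraries. Purple points are the 6931 genes called in both in the same direction, orange points the 310 called in opposite directions, grey points the rest, and the dotted line marks equal changes. TENM2 and PKHD1 changed strongly in both, and COL5A1 and FN1 lie among the opposite genes.

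Compared directly, the knockdowns differed in 5186 genes, 2628 higher and 2558 lower with shAKR1B1 than with shSORD, of which 878 differed at least 2-fold (418 higher, 460 lower). In the main fit 15.5% of all tested genes were higher and 15.1% lower with shAKR1B1 than with shSORD, the shares to set beside the list counts below. With only the compared groups in the fit, 4121 genes were called. The largest differences upward were HHIP (16.7-fold higher with shAKR1B1), CLVS1, a lipid-binding protein of endosomes (7.15-fold), BPIFB1 (6.78-fold), SCIN (6.58-fold) and the protease inhibitor CST1 (6.37-fold). The largest downward were COL5A1 (12.4-fold lower, 9.81 ± 0.497 against 121.3 ± 19.4 CPM), the neuronal pentraxin NPTX1 (10.5-fold), IGFN1 (10.2-fold), SPOCK1 (9.7-fold) and DOCK2 (8.9-fold), all with adjusted p at or below 2.78e-08. Against control, COL5A1 was 1.21-fold higher with shSORD (adjusted p = 0.0179), a call that ended without control replicate 1, control replicate 2 or shSORD replicate 2 (adjusted p = 0.0622, 0.0784 and 0.0687). Epithelial markers did not differ as a list (8 higher and 7 lower of 35, 9 and 8 adjusted over the list alone; adjusted p = 0.992), and CDH1 differed by -0.05 (SE 0.0604, adjusted p = 0.548). Mesenchymal markers were lower with shAKR1B1, 23 of 39 against 4 higher (25 and 4 adjusted over the list alone; median -0.61, adjusted p = 7.38e-14, with an estimated correlation adjusted p = 0.0933), as were fibroblast markers, 7 of 9 with 0 higher (8 and 0 adjusted over the list alone; median -2.03, adjusted p = 5.4e-07, with an estimated correlation adjusted p = 0.162). CDH2 was 3.17-fold lower, VIM 1.23-fold lower and FN1 3.13-fold higher with shAKR1B1. ZEB2 was 2.25-fold and TWIST1 1.59-fold higher, and SNAI1 (log2 difference -0.25, adjusted p = 0.162) and SNAI2 (1.11, adjusted p = 0.204, but 0.00601 without shSORD replicate 3) did not pass.

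TGF-beta target genes were lower with shAKR1B1 than with shSORD for 17 of 29 and higher for 4 (19 and 4 adjusted over the list alone; median -0.34, adjusted p = 1.36e-22). PMEPA1 was 5.04-fold, HMOX1 4.76-fold and IL11 4.02-fold lower. TGFB1 did not differ (log2 difference -0.05, SE 0.0819, adjusted p = 0.708), whereas TGFB2 was 1.72-fold lower (adjusted p = 0.000148). Ligands, receptors and SMADs were lower for 8 of 19 and higher for 1 (9 and 1 adjusted over the list alone; adjusted p = 0.000531), matrix and integrin genes for 17 of 37 and higher for 6 (19 and 6 adjusted over the list alone; adjusted p = 1.06e-09) and p53 targets for 19 of 25 and higher for 3 (adjusted p = 1.66e-06). These 4 lists also passed with an estimated correlation (adjusted p = 0.0173 for the targets, 0.0401, 0.00801 and 0.0173). CDKN1A was 2.32-fold lower with shAKR1B1 and MKI67 1.16-fold higher, the latter a call that ended without shSORD replicate 1 (adjusted p = 0.0523).

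Several other lists passed in the direct comparison with the preset correlation and not with an estimated one. Oxidative phosphorylation genes were higher with shAKR1B1 for 25 of 73 and lower for 1 (adjusted p = 0.00343, estimated correlation p = 0.425), and G2/M genes for 10 of 32 with 0 lower (0.00719 and 0.631), which ended without shSORD replicate 1 (adjusted p = 0.0855). Alveolar and airway markers had 4 higher and 3 lower of 14, with a median of -0.16, a mean of 0.24 and a test direction of up (adjusted p = 0.0022, estimated correlation p = 0.245, and 0.168 with no expression filter). MUC5AC and MUC5B were higher with shAKR1B1 by log2 differences of 2.45 and 2.38. Interferon-stimulated genes were lower for 16 of 33 and higher for 4 (adjusted p = 0.0274, estimated correlation p = 0.168, and 0.069 without shSORD replicate 3), and NF-kappaB and cytokine genes higher for 9 of 25 and lower for 6 (9 and 7 adjusted over the list alone; 0.0427, with an estimated correlation 0.364, without shSORD replicate 3 0.141, with no expression filter 0.0992 and with the GC offset 0.109). Fatty acid synthesis had 8 of 21 lower and 0 higher (adjusted p = 0.0473, estimated correlation p = 0.168). This list lost its call without control replicate 1, 2 or 3, shAKR1B1 replicate 1 or 2, or shSORD replicate 1 or 3 (adjusted p from 0.0516 to 0.0912). It also lost it with RLE scaling (0.0511), with the stricter filter (0.0608) and with only the compared groups (0.07). NRF2 targets (15 of 30 higher, 4 lower, 17 and 4 adjusted over the list alone; 0.0435 and 0.298) lost theirs without control replicate 3, shAKR1B1 replicate 2, or shSORD replicate 1 or 3 (0.0556 to 0.0842), with the stricter filter (0.0608) and with only the compared groups (0.0814). ATF4 and unfolded protein response genes (12 of 30 lower, 4 higher, 13 and 5 adjusted over the list alone; 0.0444 and 0.358) lost theirs without control replicate 3, shAKR1B1 replicate 1 or 2, or shSORD replicate 2 or 3 (0.0506 to 0.107), with the stricter filter (0.0608) and with only the compared groups (0.0516). The calls of fatty acid synthesis and NRF2 targets also ended when the replicate number was a block (both 0.0638).

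The remaining lists did not differ by the test. Counts higher and lower were 3 and 1 of 9 polyol and fructose genes (4 and 1 adjusted over the list alone; adjusted p = 0.258, and, higher, 0.0194 without AKR1B1 and SORD in the list and 0.043 with the GC offset), 4 and 12 of 24 YAP/TAZ targets (4 and 13 adjusted over the list alone; 0.124, and 0.0102 with no expression filter), 6 and 7 of 23 glycolysis genes (8 and 7 adjusted over the list alone; 0.38) and 3 and 1 of 13 pentose phosphate genes (5 and 1 adjusted over the list alone; 0.447). They were 5 and 1 of 11 hexosamine genes (0.46), 4 and 2 of 27 TCA cycle genes (3 and 2 adjusted over the list alone; 0.294), 3 and 2 of 25 cholesterol synthesis genes (0.992), 8 and 7 of 25 hypoxia genes (0.992), 2 and 4 of 26 G1/S genes (0.888) and 6 and 4 of 17 stem cell markers (0.992).

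**Figure D4:**
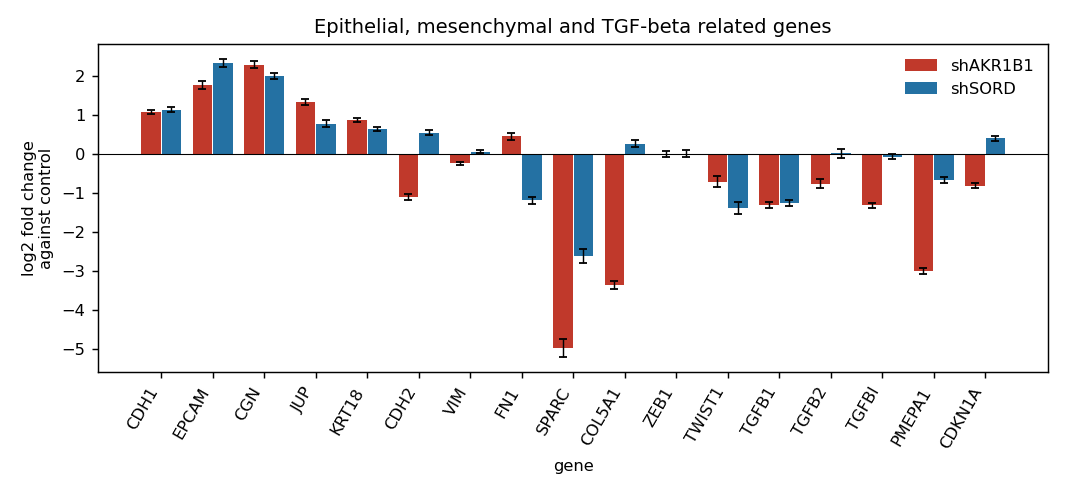
Log2 fold changes against control of 17 genes of epithelial and mesenchymal state and TGF-beta signalling, red for shAKR1B1 and blue for shSORD, with SE as error bars. CDH1, EPCAM and CGN are higher and TGFB1 lower in both, whereas CDH2 and CDKN1A are lower with shAKR1B1 and higher with shSORD.

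Markers of other cell types and lists sensitive to RNA quality were read in the same way. Of the leukocyte markers 4 passed the filter, too few for a list test: lysozyme (LYZ) rose with shAKR1B1 and shSORD (log2 fold changes 3.91 and 2.34), ITGAM rose (0.87 and 1.30) and CD14 fell (-0.83 and -1.38). Of the endothelial markers 1 passed, ESAM, at -0.60 with shAKR1B1 and 0.45 with shSORD. The shAKR1B1 value lost its call without shAKR1B1 replicate 2 (adjusted p = 0.0579), and the shSORD value without control replicate 2, control replicate 3 or shSORD replicate 1 (adjusted p = 0.0564, 0.0862 and 0.0574) and with DESeq2 (0.0667). Mitochondrially encoded mRNAs had 3 higher and 2 lower of 13 with shAKR1B1 (adjusted p = 0.85), 4 and 4 with shSORD (0.827) and 3 and 1 between the knockdowns (0.378). Replication-dependent histones had 2 higher and 3 lower of 11 with shAKR1B1 (0.911), 3 and 2 with shSORD (0.805) and 0 and 2 between the knockdowns (0.46). Cytosolic ribosomal protein genes had 4 higher and 11 lower of 60 with shAKR1B1 (1 and 9 adjusted over the list alone; 0.597), 7 and 14 with shSORD (6 and 12 adjusted over the list alone; 0.614) and 2 and 5 between the knockdowns (0 and 0 adjusted over the list alone; 0.992).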

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

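All explanations in this part were tested after the results were seen. TGF-beta target, mesenchymal and matrix genes differed between the knockdowns. The median of the mesenchymal list differed by -0.606 (adjusted p = 0.0933 with an estimated correlation) and that of the matrix and integrin list by -0.15 (adjusted p = 0.00801 with an estimated correlation). HMOX1 differed by -2.25, COL4A2 by -1.61, LTBP2 by -1.18, COL5A1 by -3.63, CDH2 by -1.66, FSTL1 by -1.32 and COL1A1 by -2.03 on the log2 scale, each lower against control with shAKR1B1 and higher with shSORD. The shSORD rise ended for COL5A1 without control replicate 1 (adjusted p = 0.0622), control replicate 2 (0.0784) or shSORD replicate 2 (0.0687), and for COL4A2 without the same libraries (0.126, 0.0829 and 0.14).

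A lower TGFB1 transcript level does not account for the difference in TGF-beta targets, since its log2 difference between the knockdowns was -0.047 (SE 0.0819). A lower TGFB2 transcript level goes with that difference, at a log2 difference of -0.780 (SE 0.119). Transcript levels do not show secreted or active ligand, so a difference in the activity of either ligand remains open. GC content of the transcripts did not explain the difference in targets, as the list kept an adjusted p of 2.45e-22 with a GC offset. Fibroblasts in the shSORD cultures add no counts to the shAKR1B1 and control libraries, between which the list was lower (adjusted p = 4.31e-09, but adjusted p = 0.116 with an estimated correlation). The shSORD libraries enter that test only through the filter, the scaling and the shared dispersion. Whether a few fibroblasts contributed to the collagen rise with shSORD remains open: over the 3 shSORD libraries DCN had 6 counts, 1.82% of those of COL1A2, against 2 in control libraries, whereas LUM had 56 against 2, PDGFRB 89 against 21, POSTN 47 against 5 and BGN 80 against 4, PDGFRA 11 against 21 and FAP 2 against 0. LUM also had 26 counts with shAKR1B1.

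Other genes also moved in opposite directions. Higher with shAKR1B1 and lower with shSORD were CLVS1 (log2 difference 2.84), CST1 (2.67), FN1 (1.65), MUC5B (2.38) and AKR1B10 (0.63), where the fall of CLVS1 with shSORD ended without control replicate 1 (adjusted p = 0.128), shSORD replicate 1 (0.128) or shSORD replicate 2 (0.0511), and with DESeq2 (0.0727), only the compared groups (0.0772) and the stricter filter (0.0502). Lower with shAKR1B1 and higher with shSORD were NPTX1 (-3.39), IGFN1 (-3.35), DOCK2 (-3.15), CDKN1A (-1.22) and ESAM (-1.05). The call of ESAM ended with shAKR1B1 without shAKR1B1 replicate 2 (adjusted p = 0.0579), and with shSORD without control replicate 2 (0.0564), control replicate 3 (0.0862) or shSORD replicate 1 (0.0574), and with DESeq2 (0.0667).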

How the results depend on the processing

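Among the genes followed one by one, the lists fixed in advance and the totals, no call reversed its direction under any alternative. With each library left out in turn, the genes called ranged from 8481 to 10712 for shAKR1B1 against control, 8383 to 10127 for shSORD against control and 3840 to 6731 between the knockdowns, and 5967 to 7525 were shared in direction. AKR1B1 stayed between -3.27 and -3.16 and SORD between -2.35 and -2.26. DESeq2 called 9132, 8946 and 4789 genes, and the GC offset, chosen after the data were seen, 10583, 10493 and 6583. With only the compared groups in the fit, 11094, 8763 and 4121 genes were called. Replicate numbers do not state a pairing. Libraries of the same number correlated at 0.102, 0.193 and 0.144 between the knockdowns, against -0.175 to 0.0322 for different numbers, and stayed below 0.1 between control and either knockdown, so a pairing of the knockdowns is left open. With the number as a block, 9994, 9817 and 5643 genes were called. In the direct comparison the block ended the list calls of fatty acid synthesis and NRF2 targets (both adjusted p = 0.0638) and added KRT19 (0.0283), MCM2 (0.0488), GPX2 (0.0435) and F10 (0.0431). With the stricter filter, which tests 13669 genes and so fewer by construction, 1190, 1086 and 458 changed at least 2-fold, against 2093, 1881 and 878. Of the calls against control, 51.5% with shAKR1B1 and 52.6% with shSORD were then higher, against 48.4% and 48.7% in the main fit. The split of directions, and very small changes, thus depend on the filter and scaling. Without a filter the covariance of the knockdowns was 0.942 against 0.434. An estimated correlation removed 26 list calls, among them epithelial markers (adjusted p = 0.0973 with shAKR1B1, 0.159 with shSORD), mesenchymal markers (0.295, and 0.0933 between the knockdowns) and TGF-beta targets with shAKR1B1 (0.116). The test fry, which asks whether a list moves one way on balance and not whether it moves more than other genes, added 30. Without a filter, 9 list calls were gained and 4 lost. The 3 lists written later were tested only with the preset and the estimated correlation. The polyol list with shSORD also lost its call with no filter (0.0611), the stricter filter (0.0637), only the compared groups (0.0518), the block (0.0505) and the GC offset (0.051).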

Other observations

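Genes of liver and intestine rose in both knockdowns. The lists were written after coagulation, renal and gut genes were seen among the largest rises, and the tests were stated before they were run. Of 28 measured liver-type secretory and metabolic genes, 23 rose and 1 fell with shAKR1B1 (median log2 fold change 2.05, adjusted p = 6.36e-28, with an estimated correlation adjusted p = 0.00737), and 21 rose and 1 fell with shSORD (1.04, adjusted p = 4.38e-16, with an estimated correlation adjusted p = 0.0312). The fibrinogen genes FGA, FGB and FGG rose by 2.92, 3.55 and 3.14 with shAKR1B1 and by 2.07, 3.00 and 2.30 with shSORD, vitronectin (VTN) by 2.21 and 2.65, and coagulation factor F5 by 3.10 and 2.71. CPS1, the first enzyme of the urea cycle, fell (-0.72 and -0.86). Of 21 intestinal epithelial genes, 17 rose and 0 fell with shAKR1B1 (median 2.1, adjusted p = 3.79e-26, with an estimated correlation 0.00737) and 13 rose and 2 fell with shSORD (0.923, adjusted p = 4.92e-14, with an estimated correlation 0.0312). The microvillus proteins VIL1 and MYO1A rose by 3.44 and 3.81 with shAKR1B1 and by 2.99 and 3.04 with shSORD, and the cadherin CDH17 by 3.41 and 3.16.

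Transcription factors of liver and intestine rose with them, 11 of 15 with shAKR1B1 (median 0.842, adjusted p = 2.57e-09) and 9 of 15 with shSORD (0.633, adjusted p = 3.54e-05), with 2 lower in each. HNF4A rose by 1.44 and 1.32, while NR5A2 fell (-0.84 and -0.74). Between the knockdowns the liver-type list was higher with shAKR1B1 for 17 of 28 and lower for 4 (median 0.698, adjusted p = 3.02e-09), the intestinal list for 15 of 21 and lower for 2 (0.768, adjusted p = 1.75e-09) and the factors for 9 of 15 and lower for 0 (0.42, adjusted p = 0.000356), each with adjusted p = 0.0589 with an estimated correlation. Only 28 of 47 liver-type and 21 of 37 intestinal genes passed the filter. Albumin (ALB) averaged 0.0265 CPM in control cells, 0.519 CPM with shAKR1B1 (log2 fold change 4.11, adjusted p = 1.72e-05) and 0.0845 CPM with shSORD (1.55, adjusted p = 0.12, and 0.0415 without shSORD replicate 2), so its rise left it at a low level. The intestinal factor CDX2 was not called in either (log2 fold changes 0.58 and -0.46, adjusted p = 0.0636 and 0.187), although with shAKR1B1 it passed with only the compared groups (0.0384) and with the GC offset (0.0314). The values are consistent with a rise of part of the hepatic and intestinal genes (medians 2.05, 2.1, 1.04 and 0.923), and they do not show which factor drives it.

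Long non-coding genes tended upward in both knockdowns. Of 2122 tested, 673 rose and 249 fell with shAKR1B1 (median 0.240) and 661 rose and 199 fell with shSORD (0.247), against medians of -0.03 and -0.04 in 13429 protein-coding genes. Protein-coding genes matched in level had mean medians of 0.146 and 0.216, with highest values of 0.239 and 0.313 in 1000 draws. Low expression therefore accompanies much of the shift with shAKR1B1, and with shSORD the observed median lay within the range of the matched draws. Genomic DNA or unspliced RNA could contribute, a test stated before it was run, as genes below the filter summed to 470.3 ± 3.35 CPM in control cells, 528.3 ± 12.5 CPM with shAKR1B1 and 562.7 ± 22.7 CPM with shSORD, the last 1.2 times control. Deeper sequencing did not account for it, at 0.997 and 1.01 times the control totals, a test chosen afterwards.

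The shared direction of the knockdowns has more than 1 possible source. Noise of the shared controls did not reach it in a test chosen afterwards: the highest covariance in 100 simulated unchanged sets was 0.0285, against 0.434. A particular state of the single control population may contribute, since every change is measured against it. In a test stated before it was run, 28.4% of the 6931 shared genes also differed between the knockdowns, which does not bound such a contribution. A common consequence of lower polyol flux, which was not measured, and a response to any active hairpin remain open as well. Exchanging libraries between groups, also tried afterwards, gave too few splits for a share under 0.05: of 10 splits in each comparison only the real 1 gave calls (9716, 9565 and 5186), and the highest other gave 0.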
